A study of Danio rerio with 6 samples.

How the data were processed

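Whole zebrafish larvae were collected at 72 hours post fertilization, per the labels. The control group held 3 libraries of the wild-type AB strain, and the other group held 3 libraries of larvae injected at the 1-cell stage with an antisense morpholino named for GJB2, a gap junction gene known for its role in hearing. A morpholino is a synthetic oligonucleotide that binds RNA and blocks its translation or splicing. Per the labels' protocols, mRNA was selected with poly-T beads. Whether the libraries and the counting keep strand is not given in the sources used here, so reads of a gene and of an antisense partner were not told apart. The labels do not say how many larvae were pooled per library or whether the libraries of a group came from separate clutches, so p-values measure the spread between these libraries, which may be partly technical. No library of larvae injected with a control oligonucleotide was analysed here.

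The deposited table holds, for each of 53709 rows, the read counts, FPKM and TPM of the 6 libraries, with a gene symbol and, for 37672 rows, a chromosome, start, end and strand. The read counts are whole numbers per row, not normalized, as deposited by the authors. The FPKM values deposited by the authors are counts scaled by a row's length and by the library's reads, and the TPM values deposited by the authors are scaled to the same sum in each library. In all 22228 rows compared, the length implied by counts and FPKM was the same in each of the 6 libraries within a tolerance of 1e-06. FPKM therefore adds nothing to the counts about differences between libraries. The implied lengths were used below to match lists on gene length. Per the submitters' processing notes, the tools were HISAT2, StringTie 1.3.1 and RSEM on the GRCz11 build, with no role or order given; coordinates below are 1-based on GRCz11 as the deposited table gives them. All columns of per-library values belonged to the 6 libraries.

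A feature of the table shapes the measurements. Of its rows, 16024 carry the symbol of another row with a numeric suffix (actb1 and actb1_1, for example) and no coordinates; they are taken here as further annotated copies of the same gene, an inference from the names alone. They held between 5.45% and 5.73% of the counts of a library. Reads of 1 gene can be shared out among such rows according to which copy each read resembles most, so a row can gain or lose reads with no change in the RNA of the gene. The test fixed before the data were examined used the rows as deposited. A second version, chosen after seeing the data, summed the rows of each gene (37685 genes in the table, 22247 tested) before the same test, and it is given for lists and named genes whose call it changed.

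Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept with filterByExpr at its defaults (min.count 10, min.total.count 15), which left 24652 rows; library sizes were scaled with TMM. A quasi-likelihood model with robust estimation compared the 3 morpholino libraries with the 3 controls, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. A row was called at an adjusted p under 0.05. Fold changes are morpholino over control on the log2 scale with a standard error; levels are TMM-scaled CPM (counts per 1e6 counts) as mean ± SD over 3 libraries. All adjusted p-values of single genes come from this test unless another is named.

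Before the data were examined, 39 gene lists were fixed for apoptosis, mitochondria, the ear, stress, immunity, growth and the tissues of a larva. They served also as cell type markers. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 39 lists, then with the correlation estimated per list, and with fry. fry asks whether the genes of a list move on balance one way, or in its mixed form in either direction, and neither form compares a list with other genes. The number of members past the threshold is also given adjusted over the list alone. The list of genes of the mitochondrial genome was matched by chromosome, because the table names these rows ND1 or COX1 and not by the prefix the list assumed. In the rows as deposited, each list member stands for the row of its plain symbol, and rows with a suffix are not counted. Symbols were matched to the table directly or through synonyms of a RefSeq table of the GRCz12tu assembly, used for names only.

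Genes named in the text follow a rule fixed in advance. It takes the targeted gene, and connexins that pass the test or have the highest control level. It takes the 10 largest rises and 10 largest falls among called rows whose groups do not overlap in CPM, with a mean of at least 1 CPM and a proper symbol. Of each list described it takes up to 4 members with the smallest adjusted p past the threshold, or up to 2 given as values where no member passed. It also takes mdm2, cdkn1a, ccng1, bbc3, baxa, casp3a, casp9, apaf1, bcl2a and cycsb whatever their result. Some results that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen. Which zebrafish transcript the morpholino matches was not analysed here, since no transcript sequences were used; the gene gjb8, listed in RefSeq with the synonym cx30.3, was taken as the closest named candidate and this remains uncertain.

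The main test, the list test and the test of reads between rows were run on simulated counts with known answers; the other tools were not. With counts drawn from the means, library sizes and gene-wise dispersions of the 6 libraries for 24298 rows, edgeR recovered 31.3% of 67 rows changed 1.5-fold, 59.7% of 67 changed 2-fold and 84.8% of 66 changed 4-fold, and made 8 calls when nothing was changed. Of the 137 calls in that simulation, 20 were false, above the 5% aimed at. A second simulation with dispersions from the fitted trend, run after that result was seen, gave 4 false calls of 127. The share of false calls may therefore exceed the nominal level among rows that vary strongly between replicates. The list test found a list shifted by -0.3 on the log2 scale among the 39 and called no other, in simulated data with independent genes. The test of how a gene's reads divide among its rows, fitted with limma to the first row's log ratio to the others, recovered 52% of 100 changed genes among 2396 with 2 false calls. The rows of a gene were drawn independently there, so reads passing between rows within a group were not simulated.

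Total counts were 14582030 to 16725570 in the control libraries and 15720292 to 19743658 in the morpholino libraries. The counts of each pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 9.24 and 15.6, so no library was counted as a copy of another. Exact permutation tests of 3 against 3 libraries are two-sided and cannot go below p = 0.1. Confidence intervals are at the 95% level and cover counting error only. The alternatives fixed in advance were other scalings (RLE, upper quartile, total counts), DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(TPM + 1), no filter or at least 50 counts in 3 libraries, a 2-fold minimum, an adjusted p under 0.01, the replicate number as a block, removal of mitochondrial genes and the 20 most abundant genes, and leaving out each library.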

Results

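Gene expression was measured by poly-A RNA sequencing in whole larvae at 72 hours post fertilization, in 3 control libraries of the AB strain and in 3 libraries of larvae that had received the GJB2 morpholino at the 1-cell stage. The total counts of control libraries 1 to 3 were 14582030, 16539532 and 16725570, and those of morpholino libraries 1 to 3 were 17916896, 19743658 and 15720292. The title of the series places the question in hereditary deafness and mitochondrial apoptosis, so the knockdown target, apoptosis genes, mitochondrial genes and genes of the ear were examined first. The first principal component held 38.2% of the variance of log2 CPM and separated the groups, with the controls between -42.6 and -37.5 and the morpholino libraries between 38.5 and 41.7.

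The candidate for the targeted gene was near the limit of detection, and whether it is the target remains uncertain. The connexin gene gjb8, the closest named candidate for the target, was listed at 0 counts in all 6 libraries, and its second row, gjb8_1, held 7, 8 and 11 counts in the controls and 114, 14 and 16 in the morpholino libraries. The level of gjb8_1 was 0.540 ± 0.0984 CPM against 2.68 ± 3.13 CPM (SD, n = 3 per group), a log2 fold change of 2.29 ± 0.98 (SE) that did not pass the test (adjusted p = 0.238). Without morpholino library 1 it was 0.67 (adjusted p = 0.515). A morpholino that blocks translation need not lower its target RNA, so these counts do not check the labels. Of 29 connexin genes tested by the row of their plain symbol, 2 rose and none fell, also 2 when adjusted over the list alone. The list was not called (camera adjusted p = 0.105). The row of gjd1a rose by 2.31 ± 0.17 on the log2 scale, but gjd1a_1 fell by 0.91 (adjusted p = 0.00624), and their sum did not pass (0.28 ± 0.10, adjusted p = 0.142). The most abundant connexin, gja1b, stood at 139 ± 3.35 and 149 ± 10.5 CPM (adjusted p = 0.419).

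Beyond the candidate target, the largest calls among genes with a single row were higher plekhs1.1, a pleckstrin homology gene, and ifi44a4, an interferon-induced gene, and lower paox, a polyamine oxidase. plekhs1.1 (chromosome 12, 30517386 to 30523236) rose from 1.34 ± 0.428 to 9.37 ± 0.634 CPM, a log2 fold change of 2.79 ± 0.23 (adjusted p = 1.4e-04). ifi44a4 rose by 4.60 ± 0.70, on 5 counts over the 3 controls and 142 over the 3 morpholino libraries, a ratio of 25.5 with a 95% counting interval of 10.7 to 79.6. A single row does not exclude reads shared with related genes. plekhs1.1 is described as a tandem duplicate, and ifi44a4 has the relative ifi44a5. paox (chromosome 13, 30655172 to 30662403) fell by 3.33 ± 0.54, from 6.0 ± 2.2 to 0.596 ± 0.395 CPM (adjusted p = 0.0126), a call lost without morpholino library 2. Over the whole table, 2049 of 24652 rows were called, 930 higher (3.77%) and 1119 lower (4.54%), and 693 of these changed at least 2-fold. The counts of called list members below are to be read beside these shares. With the rows of each gene summed, 1378 of 22247 genes were called, 641 higher and 737 lower. Leaving out control libraries 1 to 3 in turn gave 1553, 1032 and 1215 called rows, and leaving out morpholino libraries 1 to 3 gave 1120, 1546 and 1128. With rows summed the range was 579 to 1070 genes.

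**Figure D1:**
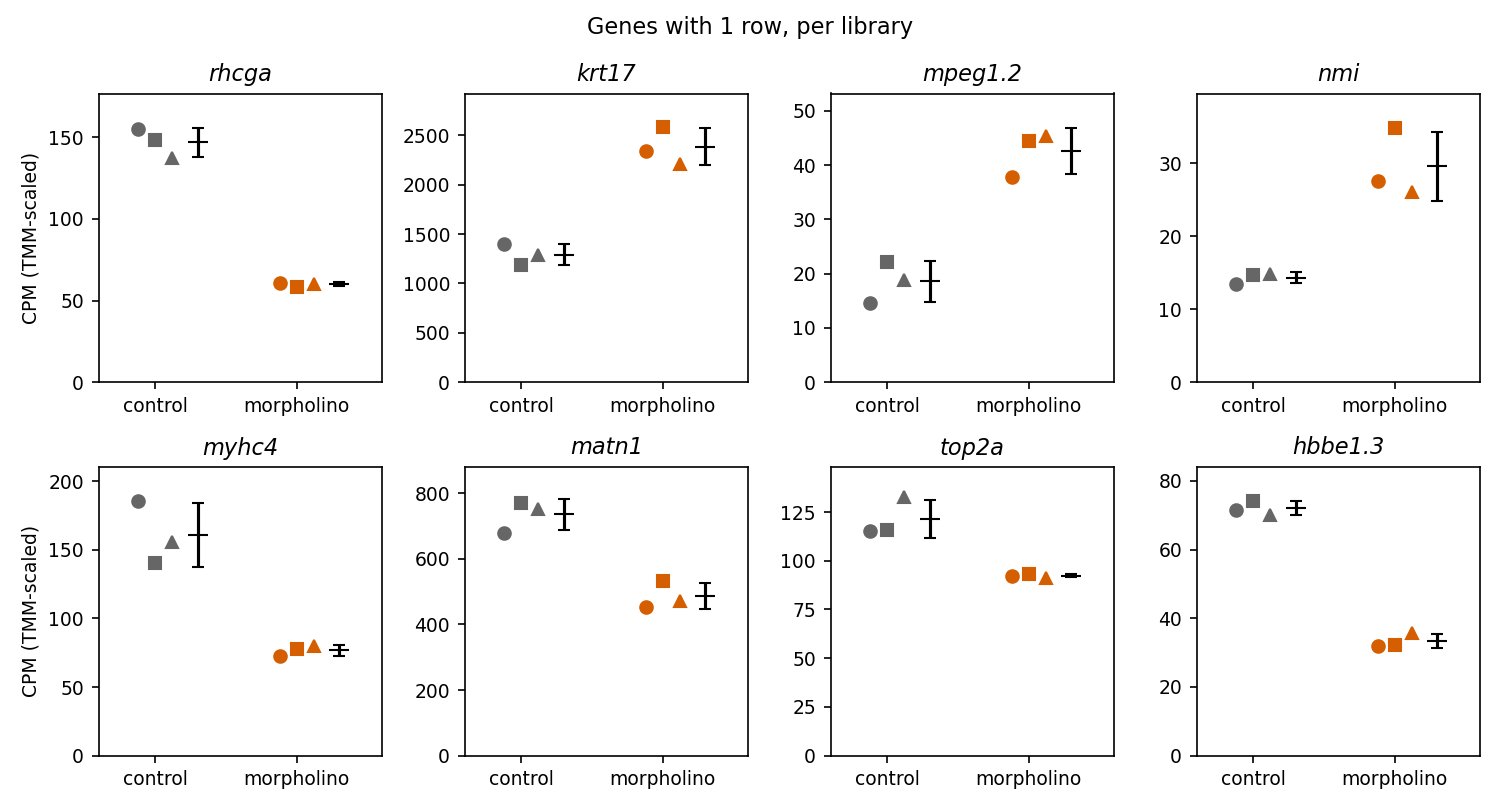
TMM-scaled CPM of 8 genes with a single row, chosen for drawing after their values were seen; each point is 1 library (circle, square and triangle for replicates 1, 2 and 3), and the bar shows mean ± SD of 3 libraries. krt17, mpeg1.2 and nmi lie higher in the 3 morpholino libraries, and rhcga, myhc4, matn1, top2a and hbbe1.3 lie lower, with no overlap between the groups.

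Most of the largest calls were made on genes with more than 1 row, and there the rows often moved apart. The largest rises by the fixed rule were hspa4b_2, psmc6, ifi44a4, npas2_1, selenot2, crybgx, vps37a, capn2l, plekhs1.1 and rnf130_1, with log2 fold changes between 2.63 and 5.42. The largest falls were ctrb.1_1, mat2al, amt_1, ttc33_1, atp5meb, fam91a1, tcima_2, akirin1_1, nupr1b and paox, between -6.12 and -3.33. Of the rises, hspa4b, psmc6, crybgx, vps37a and rnf130 were not called once their rows were summed, and capn2l shrank from 2.92 to 0.31. The sum of psmc6 still stood at 2.06 ± 0.47 (adjusted p = 0.0984), and psmc6_1 changed little (-0.19 ± 0.17). Of the falls, ctrb.1, amt, atp5meb and akirin1 were not called when summed, mat2al shrank to -0.41, and nupr1b turned from -3.50 to 0.32 (adjusted p = 0.0483). npas2, a clock transcription factor, selenot2, a selenoprotein, ttc33, fam91a1 and tcima were called in the same direction when summed, at 3.19, 3.33, -4.77, -4.53 and -2.25. For selenot2, ttc33 and fam91a1 the called row held all counts of the gene, so summing left the counts as they were and was no test of shared reads. Of 2396 genes with at least 2 tested rows, 588 had a called row. In 470 of the 588, rows moved in opposite directions, and 108 of the 588 (18.4%) were called when summed. The split of reads between the first row and the others changed in 436 of the 2396 genes (limma, adjusted p under 0.05). Tandem copies such as the globin, opsin, mpeg1 and ctss2 genes can exchange reads in the same way and are uncertain to that extent. The beta-actin gene actb1, chosen after its values were seen, had the same pattern. Its first row fell from 2128 ± 295 to 807 ± 77.2 CPM, actb1_1 rose from 786 ± 113 to 2547 ± 334, and the sum did not pass the test (0.20 ± 0.09, adjusted p = 0.200).

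**Figure D2:**
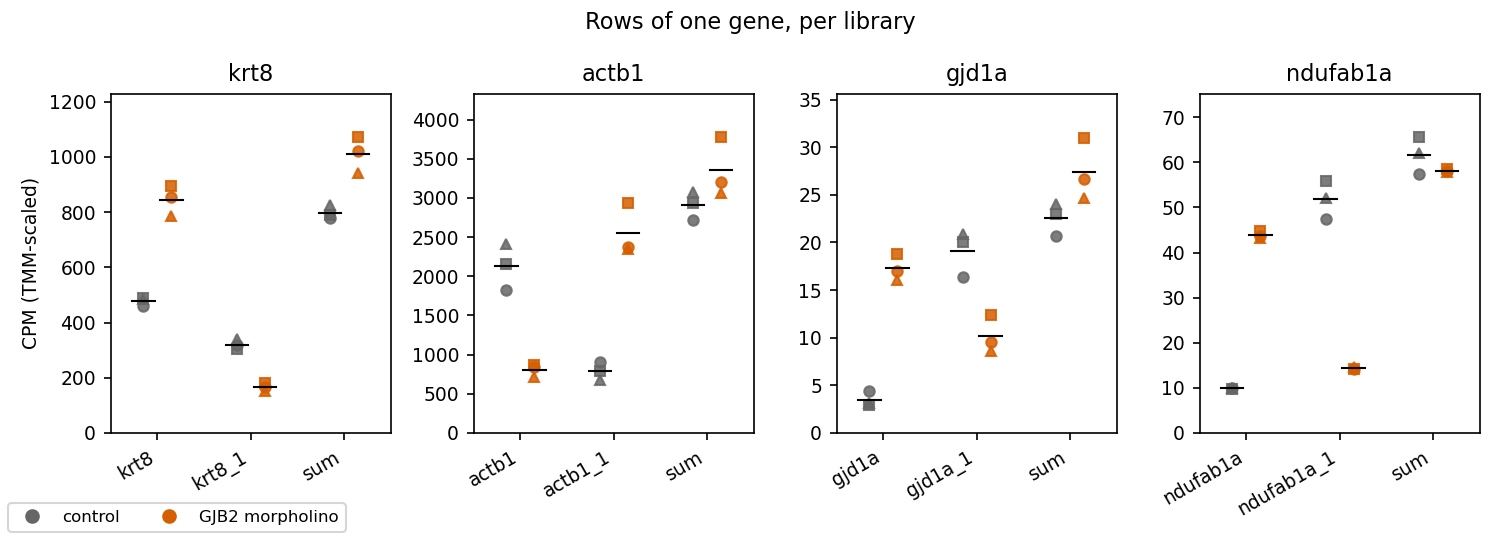
TMM-scaled CPM of each row, and of the sum of rows, for krt8, actb1, gjd1a and ndufab1a; points are libraries (circle, square and triangle for replicates 1, 2 and 3) and black lines are means of 3. One row of ndufab1a lies at 9.90 CPM in the controls and 43.9 in the morpholino libraries and the other at 51.8 and 14.3, while their sums are 61.7 and 58.2.

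Few genes of mitochondrial apoptosis changed, and they did not move one way. Of 44 intrinsic apoptosis genes tested, 2 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone. This list was not called (camera adjusted p = 0.190). For comparison, 3.77% of all tested rows were called higher and 4.54% lower. diabloa, which encodes a mitochondrial protein that antagonizes inhibitors of apoptosis, rose by 0.47 ± 0.09, from 60.4 ± 7.08 to 83.6 ± 2.65 CPM (adjusted p = 0.0104), and bada, a pro-apoptotic BCL2 family member, rose by 0.39 ± 0.10 (adjusted p = 0.0414). The gene endog, which encodes a mitochondrial nuclease, fell by 0.42 ± 0.09 (adjusted p = 0.0168). The bada call was lost without any of 5 libraries (all except control library 1) and in DESeq2, and that of endog without control library 1 or 3 or morpholino library 1 or 3. The remaining genes of the pathway did not pass. The log2 fold change of bbc3 was 0.40 ± 0.11 (adjusted p = 0.0556), of baxa -0.11 ± 0.09, of apaf1 -0.01 ± 0.08, of casp9 -0.02 ± 0.11, of bcl2a 0.22 ± 0.24 and of cycsb -0.20 ± 0.08. casp3a held 15, 272 and 51 counts in the controls and 38, 442 and 37 in the morpholino libraries, too variable to compare. Of 20 extrinsic apoptosis genes 2 rose and none fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.0515). With rows summed this list was called upward (adjusted p = 0.0249, and adjusted p = 0.310 with an estimated correlation), with 2 of 21 genes higher past the threshold. The death effector domain gene dedd1 rose by 0.55 ± 0.07 (adjusted p = 0.00115) and casp8l1, a caspase 8 relative, by 1.36 ± 0.32 on 97 against 34 counts (adjusted p = 0.0274).

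Some growth arrest genes fell, and others did not pass. gadd45ba fell by 0.74 ± 0.10 on the log2 scale, to 35.4 ± 3.84 CPM (adjusted p = 0.00169), and btg2 by 0.53 ± 0.08 (adjusted p = 0.00506). gadd45ab fell by 0.67 ± 0.16, and by 0.51 ± 0.14 with its rows summed, where it lost its call (adjusted p = 0.0570). rps27l fell by 0.28 ± 0.07. The cell cycle regulators cdkn1a (-0.18 ± 0.07) and ccng1 and the ubiquitin ligase gene mdm2 (0.17 ± 0.18) did not pass; ccng1 held 397, 1802 and 1254 counts in the controls and 106, 78 and 148 in the morpholino libraries (adjusted p = 0.0674).

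Nuclear genes for mitochondrial ribosomes and import were lower as a list. Lists of respiratory chain genes were not called. Of 94 mitochondrial ribosome and import genes none rose and 7 fell, also when adjusted over the list alone, with a median log2 fold change of -0.14 (camera adjusted p = 3.7e-06, and adjusted p = 0.222 with an estimated correlation). timm10, an inner membrane import chaperone with 1 row, fell by 0.43 ± 0.10 (adjusted p = 0.0326), lost without control library 2 or 3 or morpholino library 1 or 3. The first rows of mrps31, mrps22 and mrpl51, genes of mitochondrial ribosomal proteins, fell by 1.59, 0.68 and 0.79, and none of these passed when summed (adjusted p of 0.563, 0.132 and 0.659); with rows summed 4 of 98 genes fell. Leaving out control library 3, morpholino library 1 or morpholino library 3 left 3 falls, and control library 2 left 4. Of 99 nuclear oxidative phosphorylation genes 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.386, downward, with a median of -0.02 and a mean of 0.02). These were ndufab1a, cox6a2 and atp5meb; outside the count, the row ndufab1a_1 fell by 1.86 (adjusted p = 5.0e-06), and none of the 105 genes passed when summed in edgeR. Over the 13 protein-coding genes of the mitochondrial genome 12 were lower and 1 higher, and no gene passed in edgeR, with ND1 at -0.29 ± 0.11 and ND3 at -0.23 ± 0.09 (camera adjusted p = 0.0737). Their share of all counts was 3.11 ± 0.196% in the controls and 2.95 ± 0.441% in the morpholino libraries (exact permutation p = 0.6). Of 38 oxidative stress genes none rose and 4 fell, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.923, downward, with a median of 0.03). gpx7, txnrd3 and prdx1 fell by 0.95, 0.36 and 0.31; the row of prdx6 fell by 0.49, which was not called when summed (adjusted p = 0.836).

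Among genes listed for the ear, 4 genes of extracellular matrix proteins fell and no hair cell gene passed; in whole larvae these falls cannot be placed in the ear, and the cartilage and matrix list fell too. Of 43 inner ear and otolith genes none rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.173). tecta, which encodes the tectorial membrane protein alpha-tectorin, fell from 17.6 ± 6.14 to 6.74 ± 0.502 CPM, by 1.37 ± 0.23 (adjusted p = 0.0114), a call lost without any one of the 3 morpholino libraries. col9a1a and col9a1b, type IX collagen genes also used in cartilage, fell by 0.54 ± 0.10 and 1.00 ± 0.21, and vcanb, a versican, by 0.24 ± 0.06. Of 52 hair cell genes none passed in edgeR, over all rows or adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0581). The smallest p-values were those of espnlb (0.66 ± 0.20, adjusted p = 0.0690) and tmc2b (0.76 ± 0.23, adjusted p = 0.0712), which encodes a part of the mechanotransduction channel. With rows summed 1 of 54 hair cell genes rose, and camera called the list upward (adjusted p = 0.0247, and adjusted p = 0.194 with an estimated correlation). Of 30 lateral line genes 1 rose (si:ch73-261i21.5, adjusted p = 0.0258) and 1 fell (sox21b, by 0.59 ± 0.15), also when adjusted over the list alone (camera adjusted p = 0.810, downward, with a median of 0.01).

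The lists of cell division and of cartilage matrix held many falls. Of 60 cell cycle genes none rose and 25 fell, 34 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 5.1e-14, and adjusted p = 0.234 with an estimated correlation). kif20a and tpx2, mitotic spindle genes, fell by 0.56 ± 0.08 and 0.42 ± 0.07. top2a, a DNA topoisomerase, fell from 121 ± 9.82 to 92.4 ± 0.899 CPM (-0.39 ± 0.07, adjusted p = 0.00819), and smc4, a condensin subunit, by 0.55 ± 0.10. Of 55 genes of cartilage, bone and matrix none rose and 22 fell, and 2 rose and 25 fell when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 3.3e-05, and adjusted p = 0.438 with an estimated correlation). matn1, a cartilage matrilin, fell from 735 ± 47.7 to 486 ± 40.5 CPM (-0.60 ± 0.08, adjusted p = 0.00195). The fibrillar collagen genes col11a1b, col11a2 and col1a2 fell by 0.56, 0.73 and 0.48. With rows summed 24 and 23 genes of these lists fell. Leaving out 1 library moved the cell cycle count to between 5 (without control library 3) and 20, with 8, 8 and 7 without control library 2, morpholino library 1 and morpholino library 3, and the matrix count to between 14 (without control library 2) and 18.

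Some genes of cholesterol synthesis and of stress responses also fell. Of 37 cholesterol and lipid synthesis genes none rose and 8 fell, 10 when adjusted over the list alone, with a median of -0.19 (camera adjusted p = 9.3e-04, and adjusted p = 0.222 with an estimated correlation). Genes of the sterol pathway enzymes hmgcs1, lss, cyp51 and sqlea fell by 0.71, 0.84, 0.46 and 0.84. Of 36 genes of the unfolded protein and integrated stress responses none rose and 10 fell, 12 when adjusted over the list alone (camera adjusted p = 0.0120, and adjusted p = 0.535 with an estimated correlation). Among them xbp1, a transcription factor of the response, fell from 264 ± 12.7 to 181 ± 8.93 CPM (-0.54 ± 0.07, adjusted p = 0.00134), and dnajc3a, pdia6 and chac1 by 1.11, 0.56 and 0.38. Of 26 heat shock genes none rose and 4 fell, and 1 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.0387, and adjusted p = 0.535 with an estimated correlation). They were the mitochondrial chaperonin genes hspd1 (-0.48 ± 0.06) and hspe1 (-0.25 ± 0.06), hspa4a (-0.56 ± 0.08) and hsp90aa1.1 (-0.29 ± 0.06). The call of the unfolded protein list was lost without control library 2 (adjusted p = 0.124), where its mean turned from -0.13 to 0.017. The heat shock list was not called with rows summed (adjusted p = 0.0805), with the replicate block (0.0552), with at least 50 counts (0.0583), or without control library 3 (0.203) or morpholino library 2 (0.117). Cholesterol falls numbered 4 without control library 2 or morpholino library 1, and 5 without control library 3 or morpholino library 3. Stress response falls numbered 5 without morpholino library 1 or 3, and 6 without control library 2 or 3 or morpholino library 2.

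Several immune genes rose. Of 25 interferon response genes 5 rose and none fell, 7 when adjusted over the list alone, with a median of 0.68 (camera adjusted p = 2.8e-07, and adjusted p = 0.234 with an estimated correlation). nmi, an interferon-inducible STAT interactor, rose from 14.3 ± 0.779 to 29.6 ± 4.71 CPM (1.05 ± 0.12, adjusted p = 8.5e-04). b2m, the light chain of MHC class I, rose by 0.99 ± 0.16, stat1a by 0.38 ± 0.07 and gbp1 by 0.88 ± 0.18. Of 39 macrophage and neutrophil genes 7 rose and none fell, 9 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.00495, and adjusted p = 0.481 with an estimated correlation). mpeg1.2, a macrophage perforin gene, rose from 18.6 ± 3.77 to 42.6 ± 4.17 CPM (2.29-fold, adjusted p = 0.00223), ctss2.2 and ctss2.1, cathepsin S genes, by 1.02 and 0.88, and grna.2, a granulin, by 2.52. Of 39 complement and acute phase genes 4 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0685). Summing rows gave 5 rises and no fall, and the list was then called upward (adjusted p = 0.00964, and adjusted p = 0.400 with an estimated correlation). a2ml, itih3a.1 and serpina1, plasma protease inhibitors, rose by 0.72, 0.87 and 0.30. The row of c3b.1 fell by 0.52 and was not called when summed (adjusted p = 0.687). Without 1 library 3 to 5 interferon genes and 4 to 6 macrophage and neutrophil genes rose, with 3 interferon genes without control library 2 or 3 or morpholino library 1 or 3, and 4 macrophage and neutrophil genes without control library 1.

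Lists for skin and gut held several genes that rose, and the exocrine pancreas list held 2. Over all tested rows, 3.77% were called higher. Of 47 epidermal genes 10 rose and 3 fell, and 14 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.0343, and adjusted p = 0.438 with an estimated correlation). krt17 rose from 1292 ± 107 to 2386 ± 190 CPM (0.88 ± 0.08, adjusted p = 2.9e-04). The rows of krt8, krt4 and krt18b rose by 0.82, 1.65 and 0.72, while krt8_1 fell by 0.94 (adjusted p = 1.5e-04) and krt4_1 stood at -0.21. Of these genes krt8 was called when summed (0.34, adjusted p = 0.0167). With rows summed 7 epidermal genes rose and the list was not called (adjusted p = 0.0805). Its call was also lost with the replicate block (0.0552) and without control library 1 (0.0649), control library 3 (0.0819) or morpholino library 2 (0.0728). With rows as deposited there were 5 rises without control library 2 or 3 and 6 without morpholino library 2. Of 36 exocrine pancreas genes 2 rose and 1 fell, also when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.5e-04, and adjusted p = 0.547 with an estimated correlation). The lipase gene cel.2 and the carboxypeptidase gene cpa5 rose by 0.78 ± 0.12 and 0.72 ± 0.14, and zgc:92590 fell by 0.96 ± 0.22. Of 37 genes of the intestine and yolk syncytial layer 6 rose and none fell, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0685), with muc5.1, a mucin, mep1a.1, a meprin, cyp24a1, which degrades vitamin D, and ctsba at 0.50, 0.51, 0.77 and 0.33. Of 63 liver genes 6 rose and 2 fell, and 6 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.311). Of these cyp1a rose by 0.69 and apoeb by 0.33, and g6pc1a.2, a gluconeogenic enzyme, fell by 0.41. Of 19 endocrine pancreas genes 1 rose (pcsk1, 0.35 ± 0.08), 2 when adjusted over the list alone (camera adjusted p = 0.199). Of 36 ionocyte genes 1 rose and 2 fell, and 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.485). The ionocyte ammonia channel gene rhcga (chromosome 7, 14291349 to 14302716) fell 2.45-fold from 147 ± 8.98 CPM (-1.29 ± 0.07, adjusted p = 7.1e-06). The chloride channel gene clcn2c fell by 0.78, and kcnj1a.2 rose by 0.70.

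Lists for muscle, pigment cells and erythrocytes held mostly lower genes. Of 60 skeletal muscle genes 1 rose and 8 fell, and 2 rose and 13 fell when adjusted over the list alone (camera adjusted p = 0.0482, and adjusted p = 0.547 with an estimated correlation), a list call lost with rows summed (adjusted p = 0.0598). It was lost too with the replicate block (0.0643) and without control library 1 (0.168), morpholino library 1 (0.12) or morpholino library 3 (0.0866). myhc4, a fast myosin heavy chain, fell from 161 ± 23.1 to 76.7 ± 3.88 CPM (-1.07 ± 0.10, adjusted p = 3.2e-04), and tnnt3a and cavin4a fell by 0.53 and 0.37; myha, another myosin heavy chain, fell from 54.0 ± 7.63 to 26.2 ± 2.21 CPM. Of 24 genes of the cardiac list 1 fell (acta2, a smooth muscle actin gene, by 0.43), also when adjusted over the list alone (camera adjusted p = 0.472). Of 33 pigment cell genes 1 rose and 7 fell, and 1 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.00413, and adjusted p = 0.481 with an estimated correlation). With rows summed 4 pigment genes fell, and the list median of morpholino library 1 (0.021) lay within the range of the controls (-0.076 to 0.10). The melanosome genes tyrp1b and pmela fell by 0.58 and 0.56. The rows of tspan36 and mycbp2 fell by 1.21 and 0.97 but stood at 0.06 and 0.03 when summed. Of 36 erythrocyte genes 2 rose and 4 fell, and 2 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.234 with an estimated correlation). The erythrocyte call was lost without control library 3 (0.0537) or morpholino library 3 (0.0615). The embryonic globin genes hbbe1.3 and hbae1.3 fell by 1.11 and 0.69, and cpox, an enzyme of heme synthesis, by 0.46. The row of hbbe2 rose by 0.87 and was not called when summed (adjusted p = 0.517); summed, the list held 1 rise and 3 falls. Of 41 endothelial genes none rose and 3 fell, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.466). The genes klf2a, lyve1b and ephb4a fell by 1.14, 1.99 and 0.34. Of 32 pronephros genes none rose and 2 fell, 1 when adjusted over the list alone (camera adjusted p = 0.594), aqp8b by 0.85 and mal2 by 0.66. mal2 has 1 row and fell by 0.66 in the summed version too, where it was not called (adjusted p of 0.0512 against 0.0498).

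Among genes listed for the eye and nervous system, photoreceptor genes moved both ways and few neuronal genes changed. Of 59 photoreceptor genes 3 rose and 10 fell, and 5 rose and 12 fell when adjusted over the list alone (camera adjusted p = 0.0926). opn1mw1, a green cone opsin, fell from 523 ± 28.9 to 347 ± 15.8 CPM (-0.59 ± 0.07, adjusted p = 8.6e-04), and rbp4l by 0.48. The row of opn1lw2, a red cone opsin, fell by 1.00, and by 0.34 when summed (adjusted p = 0.0153). The row of crx rose by 1.52 and stood at -0.18 when summed, and the summed list held 1 rise and 9 falls. Of 48 lens crystallin genes 2 rose and none fell, 1 when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.00413, and adjusted p = 0.629 with an estimated correlation). They were the rows of crygm2d10 (0.63, and 0.50 when summed) and crybgx (3.18, and 0.37 when summed). Neither was called when summed (adjusted p of 0.192 and 0.511). The lens list was not called without morpholino library 2 (adjusted p = 0.370). Of 66 neuronal genes 2 rose, grin1b by 0.28 and vamp1a by 0.43, and 1 fell, stmn2b by 0.62, also when adjusted over the list alone (camera adjusted p = 0.122). Of 28 glial genes 1 fell (fabp7a, by 0.36), also when adjusted over the list alone (camera adjusted p = 0.385).

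Among housekeeping and rhythmic genes, some clock genes fell. Of 33 clock and light genes none rose and 5 fell, and 1 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.239). Summed, 1 of 35 rose (npas2) and 4 fell. nr1d2a, nfil3-6 and per1a, parts of the circadian clock or its output, fell by 0.53, 0.67 and 0.46, and the row of bmal1b fell (adjusted p = 0.00344) and was not called when summed (adjusted p = 0.0930). Of 55 glycolysis and hypoxia genes 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.385). Here ndrg1b fell by 0.83, igfbp1b rose by 0.66 and gpib rose by 0.33. The row of aldoca fell by 0.78 and was not called when summed (adjusted p = 0.447). Of 53 lysosome and autophagy genes 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.311). Among them psap rose by 0.31, ulk2 fell by 0.51, and the row of gabarapa fell by 1.16 but stood at 0.03 when summed, and the summed list held 3 rises and 1 fall. Of 93 cytosolic ribosome genes 2 rose and 1 fell, and 1 rose when adjusted over the list alone (camera adjusted p = 0.0515). With rows summed it was called upward (adjusted p = 0.0411, and adjusted p = 0.650 with an estimated correlation), with 2 rises and 2 falls among 97 genes. The ribosomal gene rpl31 rose by 0.30 and rps27l fell by 0.28. The row of rpl21 rose by 0.78 and was not called when summed (adjusted p = 0.443).

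**Figure D3:**
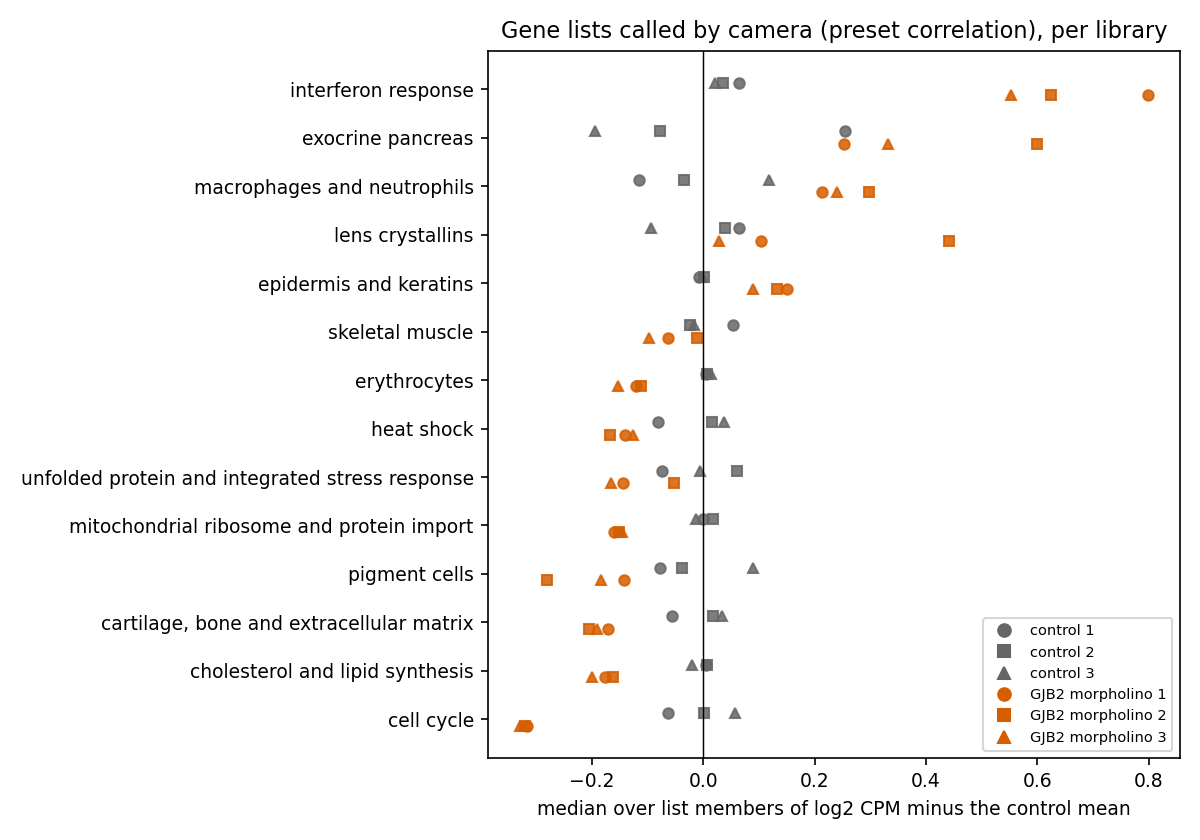
For each of the 14 gene lists called by camera at the preset correlation, the median over its members of log2 CPM minus the control mean, one point per library (circle, square and triangle for replicates 1, 2 and 3). The cell cycle list lies between -0.33 and -0.32 in the 3 morpholino libraries and the interferon list between 0.55 and 0.80, while the groups overlap for 4 lists: exocrine pancreas, lens crystallins, skeletal muscle, and the unfolded protein and integrated stress response.

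Across the 39 lists, camera called 14 at its preset correlation, 5 upward and 9 downward, 15 with rows summed, and 11 in both versions. Leaving out 1 library also gave calls to uncalled lists. Without control library 1 these were the intestine (adjusted p = 0.00431) and cytosolic ribosome (0.0038) lists, and without control library 2 extrinsic apoptosis (0.0471). Without control library 3 they were extrinsic apoptosis (0.0209), the mitochondrial genome (0.0158), complement (0.0422) and photoreceptors (0.0138). Without morpholino library 1 they were hair cells (0.0275), neurons (0.0490), cytosolic ribosome (0.00706) and intestine (0.0364). Without morpholino library 3 they were extrinsic apoptosis (0.0426), connexins (0.0320), the mitochondrial genome (0.0021), intestine (0.0424) and cytosolic ribosome (0.0369, with a mean of -0.029 against 0.061 over all libraries). None was called with an estimated correlation in camera, where the smallest adjusted p was 0.222, while fry called 11 one way and 37 in its mixed form.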

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

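Summing the rows of each gene, testing genes with a single row alone, leaving out a library with rows summed, and the counts of called list members were chosen after seeing the data; the other settings were fixed before. Called rows (2049, 930 higher and 1119 lower) stayed within 1.5 times under every scaling, tool, unit and filter, from 1676 (limma on TPM) to 2260 (no filter) (shared with the main calls: 1633 in DESeq2, 1757 in limma-voom). A 2-fold minimum left 693 (375 and 318), an adjusted p under 0.01 left 725 (329 and 396), and genes with a single row gave 1214 (558 and 656), each a smaller set by construction. Summed rows gave 1378 (641 and 737). Leaving out 1 library gave 1032 to 1553 rows (471 to 694 higher, 561 to 864 lower), or 579 to 1070 genes with rows summed (272 to 477 higher, 307 to 593 lower), with fewer libraries. The replicate numbers did not pair the libraries (correlations of deviations -0.01, 0.03 and 0.01, with 1 of 3 numbers closest to its own); the replicate block gave 1821 rows (850 and 971), or 1362 genes summed (661 and 701). Of 138 called genes taken by the naming rule, 64 kept their call under all alternatives that tested them, 87 without each library and 106 with rows summed. A gene removed by a filter, such as rnf130_1 with at least 50 counts, was not counted as lost there. The gjb8_1 difference was called by DESeq2 alone (2.30, adjusted p = 0.0316, against 0.114 to 0.515 elsewhere); the cause was not tested. With rows summed, the direction turned for rnf130_1 (-0.017), ctrb.1_1 (2.72), nupr1b (0.32), mdm2 (-0.088), ndufab1a (-0.086), crx (-0.18), tspan36 (0.063), mycbp2 (0.029) and gabarapa (0.034), because the other rows moved the opposite way. Uncalled genes crossed 0: apaf1 (0.0033 with upper quartile scaling, 7.7e-04 with at least 50 counts, -0.065 to 0.051 without 1 library), mdm2 (-0.0065 to 0.31), casp9 (-0.087 to 0.030) and casp3a (-1.63 to 2.16). Of 14 called lists 0 were called with an estimated correlation, and the replicate block ended the calls of heat shock, skeletal muscle and epidermis. The uncalled lateral line list (0.011 with rows summed), oxidative phosphorylation list (0.016 in fry, -0.032 to 0.12 without 1 library) and oxidative stress list (-0.0062 to 0.091) changed direction, as did the mitochondrial share (-0.391 to 0.0490 percentage points without 1 library); the cause was not tested. At these depths genes near 1 CPM, gjb8_1 included, rest on few counts.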

Other observations

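The tests in this part were all chosen after the result was seen, except those of gene length and of variable rows within the controls. In the version with rows summed, chosen after seeing the data, several genes outside the lists stood out. relb, a subunit of NF-kB, rose by 2.29 ± 0.38 on the log2 scale, from 0.714 ± 0.343 to 3.57 ± 1.14 CPM (adjusted p = 0.00556). hapstr1b, a stress response regulator, rose by 2.19 ± 0.15 (adjusted p = 3.3e-05), ms4a17a.8 by 2.24 ± 0.24 and rflnb by 2.01 ± 0.41. Among the falls were rabif (-2.88 ± 0.37), slc43a1a, an amino acid transporter (-2.51 ± 0.43), and slc16a8, a lactate transporter of the eye (-2.44 ± 0.40). ifi44a5 fell by 2.26 ± 0.45 while its relative ifi44a4 rose. mzt1 and ttc33 varied several-fold among the controls.

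The hatching enzyme gene he1.1 held 41, 59 and 50 counts in the controls and 15, 4 and 1 in the morpholino libraries (-3.04 ± 0.57, adjusted p = 0.0179). Over he1.1, he1.2, he1.3 and ctslb, a list written after he1.1 was seen, counts per total were 0.123 times those of the controls, with a 95% counting interval of 0.0767 to 0.189 on 24 against 175 counts, most of them from he1.1 itself.

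The first pattern is that rows of 1 gene moved apart. A shift in the total RNA of a gene leaves the split of its reads between rows as it is, and is argued against as the whole cause because this split changed in 18.2% of the 2396 genes with several tested rows. A difference in depth or scaling moves the rows of a gene alike and is argued against by the same 436 genes. A candidate explanation is that the larvae of the groups carry different variants, so that reads resemble different annotated copies. It cannot be told apart from the treatment: the Spearman rho of -0.37 between the first row's fold change and that of the other rows, over 2396 genes, restates the pattern. Uneven sharing of variants among libraries predicts more variable rows where a gene has several rows. A range over 4-fold within the controls was found in 7.96% of rows of genes with several rows against 0.234% of others (odds ratio 36.9, Fisher's exact test p = 1.4e-227). This p-value counts rows of 1 gene as independent. The range of a single row does not show whether its reads moved to another row of the gene, so the excess does not decide. If linked variants also moved genes with 1 row, called genes would neighbour each other more often than in shuffles. Within 1 Mb lay 718 called neighbours, against 693 to 737 in shuffles. The shuffle median was already 715 with 1165 genes called, so a weak excess could be missed and the count does not decide. Parents and clutches are not given in the labels, so family and treatment stay confounded.

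The second pattern is the many falls among cell cycle and matrix genes. Gene length is argued against, since 0% of 10000 lists matched on length and expression had a median as low, for either list. The split of reads between rows of 1 gene is argued against because 24 of 25 cell cycle and 22 of 22 matrix calls held when summed. Summing leaves genes with 1 row, such as top2a and matn1, as they were. These have no second row to lose reads to, and the sum does not test reads shared with related genes. A few abundant genes taking the counts would lower all others alike. This is argued against by a median of 0.0035 over all rows with total counts as the only scaling (-0.012 to 0.018 without 1 library), where the list medians were -0.33 and -0.19. A difference in developmental stage cannot be told apart from the treatment, since the hatching gland ratio of 0.123 restates the gene that prompted it, and photoreceptor genes, with a median of -0.13, went both ways. Fewer dividing cells after knockdown stays untested.

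The third pattern is the rise of interferon genes. Morpholino library 1 alone is argued against by a median of 0.69 without it, against 0.68 with it. No other library was left out in that comparison. The medians of log2 CPM minus the control mean were 0.80, 0.62 and 0.55 in morpholino libraries 1 to 3. In control libraries 1 to 3 they were 0.063, 0.036 and 0.021, which argues against any 1 morpholino library alone. More leukocytes cannot be told apart from this rise: the macrophage and neutrophil median was 0.26 against 0.68, but with an SD over members of 0.65, and 25 members were higher and 14 lower. A response to any injected oligonucleotide could give the same rise and stays open, as does a family difference in immune genes, because no control oligonucleotide library was analysed here. camera also called the interferon list in 6 of the 9 other splits of the libraries, and the cell cycle list in 6. The mitochondrial ribosome and lens lists were called in 5 each, the macrophage and exocrine pancreas lists in 3 each, and the remaining called lists in 2 at most. Each other split keeps part of the real group difference, so these counts are not a rate of false calls.

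With 10 splits of 6 libraries into 3 and 3, a share below 0.05 cannot be reached, so only values are given. Every other split mixed the groups, which keeps part of their difference and widens the spread within each side. Few called rows were therefore likely there in advance. The real grouping was the 1 split with as many calls in each case: 2049 rows against 5 at most in the others, 1378 genes summed against 5, 436 changed splits of reads against 1, and 14 lists against 12.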
